A study of Escherichia coli O157:H7 str. Sakai with 6 samples.

How the data were processed

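Total RNA from 6 samples of E. coli Sakai was sequenced after ribosomal RNA depletion. Per the labels' protocols, cultures were shaken at 37 °C in Mueller-Hinton broth with adjusted cations, 1 ml of each sample was stabilised at harvest, cells were lysed enzymatically with 1 mg/ml lysozyme and proteinase K, DNA was digested on the column, and libraries were made with a stranded kit. The submitters' processing notes name FastQC, Bowtie2 2.1.0, SAMtools, bedtools and DESeq2, without their roles. The genome build, the annotation and the counting rules, including whether counting used strand and how reads with several matches were placed, are not given in the sources used here. Transcripts that overlap, lie antisense or have near-identical copies therefore have uncertain counts.

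The authors deposited whole-number counts per locus identifier for each library, in 5433 rows, and these were used for every test. One identifier with the prefix pO157 occurs in 2 rows, which were kept apart, and 12 rows were at 0 in all libraries. The deposited normalised signal values were checked and equal the counts divided by 1 factor per library, from 0.699 to 1.78. These factors equal the size factors that DESeq2 computes from the counts of all rows. The table was used only for this check. Of the identifiers, 5344 begin with ECs, 78 rows begin with pO157, 3 with pOSAK1 and 8 with ECp. The reference table that was given describes another strain, K-12 MG1655, and 0 of the 5432 distinct identifiers matched it. For this reason the 36 gene lists (1168 symbols) that had been fixed before the data were examined could not be matched to any row and none was tested, and no check of gene length or GC content was possible.

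Libraries were compared in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Identifiers were kept by edgeR's filterByExpr with the treatment as group, which left 4950 and removed 483 rows. Libraries were scaled with TMM (factors from 0.785 to 1.24). The main test was edgeR's robust quasi-likelihood test with culture as a block and treatment as the effect, fitted to all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values are TMM-scaled, and the log2 ratio of each culture used log2 CPM with a prior count of 2, which understates the change of low counts. Groups of identifiers by prefix were tested with camera (preset correlation 0.01, and an estimated one).

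Culture was a block in the main test because the study's design text says that the 2 parts of each culture were paired, and replicate numbers were taken to name the cultures. As a check, the deviations of same-numbered libraries from their group means correlated at -0.14, 0.09 and -0.12 across identifiers, so the counts themselves do not show the pairing. Another arrangement was positive throughout, at 0.10 for control 1 with treated 2, 0.10 for control 2 with treated 3 and 0.26 for control 3 with treated 1. This arrangement was picked after all values were seen. Because deviations from a group mean cancel out within the group, negative values for some pairs of libraries go with positive values for others. No test was made between arrangements, so the values do not show another pairing. The ratios given by culture and the block therefore rest on the numbering in the labels, and the fit without the block called 28 identifiers that held all 11. The labels number 3 control and 3 treated replicates, which were read as 3 split cultures. They do not say how far apart the cultures were grown. The p-values of the main test rest on the spread between these 3 pairs, drawn toward the spread of the other identifiers. No 2 libraries of a group were alike within sampling noise (chi-square per degree of freedom from 95.9 to 874.6).

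The rule for the identifiers named in the text was fixed before the data were examined. Named transcripts pass the threshold, have a mean of at least 10 CPM and change the same way in all cultures, ordered by size of the change. Since only locus identifiers were at hand, 2 per direction are named, and where fewer than 2 pass, the one with the smallest p fills the place and is said not to have passed. Families with equal counts were found as the identifiers with at least 1000 CPM in 1 library and at least a 100-fold range over the libraries, and hierarchical clustering of log counts into 2 clusters separated them. Runs of neighbours assume that locus numbers follow the order of genes, which was tested only through the counts.

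The main test was tested on simulated counts for the 4950 identifiers and these library sizes, with 200 changed at random. It recovered 42% of 50 identifiers changed 2-fold, 98% of 50 changed 4-fold, 94% of 50 changed 8-fold and 100% of 50 changed 16-fold, with 6 false calls among 173. The simulation gave every culture the same response, took the spread from the trend with abundance alone and drew identifiers independently. Its shares therefore do not give the power in the data. There, identifiers with fitted log2 fold changes of 3.21 and 3.02 did not pass (edgeR, adjusted p = 0.112). Alternatives were the fit without the block, DESeq2, limma-voom, 3 other scalings, 2 other filters, leaving out the 10 most abundant identifiers, leaving out each culture, and, added after the data were seen, leaving out the families with equal counts or single libraries.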

Results

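Transcript levels were measured by RNA sequencing in cultures of the enterohaemorrhagic Escherichia coli strain Sakai, serotype O157:H7, in a derivative labelled stx- (stx is the gene name of the Shiga toxins). The question was which transcripts differ after exposure to Λ-5b, a compound that the study's title calls a flexicate. The replicate numbers were taken to name 3 cultures, each divided at an optical density of 0.5. One part received 0.5 µg/ml Λ-5b in methanol and the other received methanol alone, and both were harvested 40 min later, which gave 3 treated and 3 control libraries. The control libraries of cultures 1, 2 and 3 held 11389212, 11045282 and 13262999 counts, and the treated libraries held 10307311, 14067176 and 18094228. The counts are given by locus identifier, and no source used here pairs these identifiers with gene names or coordinates. Transcripts are therefore described by identifier, by the prefix of the identifier and by the order of the locus numbers, and at most 2 identifiers that rose and 2 that were lower are given.

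After exposure to Λ-5b, 10 of the 4950 tested identifiers rose and 1 fell. Each of the 11 changed by at least 2-fold and in the same direction in all 3 cultures. The rises ranged from 1.92 to 2.74 on the log2 scale, with a median of 2.19, at mean abundances from 13.4 to 770.1 CPM (counts scaled to the size of the library) over the 6 libraries. Of the identifiers that rose, 5 of 10 lay within 8 consecutive locus numbers, and the other 5 included 1 pair with adjacent numbers. The identifiers that rose and the one that fell all carried the prefix ECs, as did 4866 of the 4950 tested identifiers.

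ECs2108 showed the largest rise among those that passed the test. Its normalised level was 3.39 ± 0.449 CPM (SD, n = 3) in control cultures and 23.5 ± 9.37 CPM in treated cultures, which corresponded to a log2 fold change of 2.74 (SE 0.29). The ratio of treated to control was 6.05, 4.55 and 9.54 in cultures 1, 2 and 3. These levels rested on 26 to 45 counts in the control libraries and on 188 to 771 counts in the treated libraries. ECs2110, 2 numbers further on, rose from 24.4 ± 6.27 to 141.1 ± 18.7 CPM, a log2 fold change of 2.55 (SE 0.28), with ratios of 4.84, 4.91 and 8.40. The adjusted p was 0.036 for both (edgeR quasi-likelihood test with culture as a block, Benjamini-Hochberg adjustment).

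The transcript that fell, ECs3958, went from 26.5 ± 2.78 CPM in control cultures to 7.38 ± 0.857 CPM in treated cultures. Its log2 fold change was -1.84 (SE 0.22, adjusted p = 0.036, edgeR), and the change was nearly equal in the 3 cultures, at -1.90, -1.78 and -1.79. ECs3956 had the smallest p among the identifiers with lower values that did not pass. Its level was 21.0 ± 8.18 CPM in control and 4.0 ± 1.45 CPM in treated cultures, a log2 fold change of -2.41 (SE 0.36, adjusted p = 0.0957, edgeR). Of the 6 consecutive numbers that begin with ECs3956, a stretch whose limits were chosen after its values were seen, 5 were lower in every culture, but only ECs3958 passed. The numbers directly before and after the stretch also had log2 fold changes below 0, at -0.19 and -0.10.

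**Figure D1:**
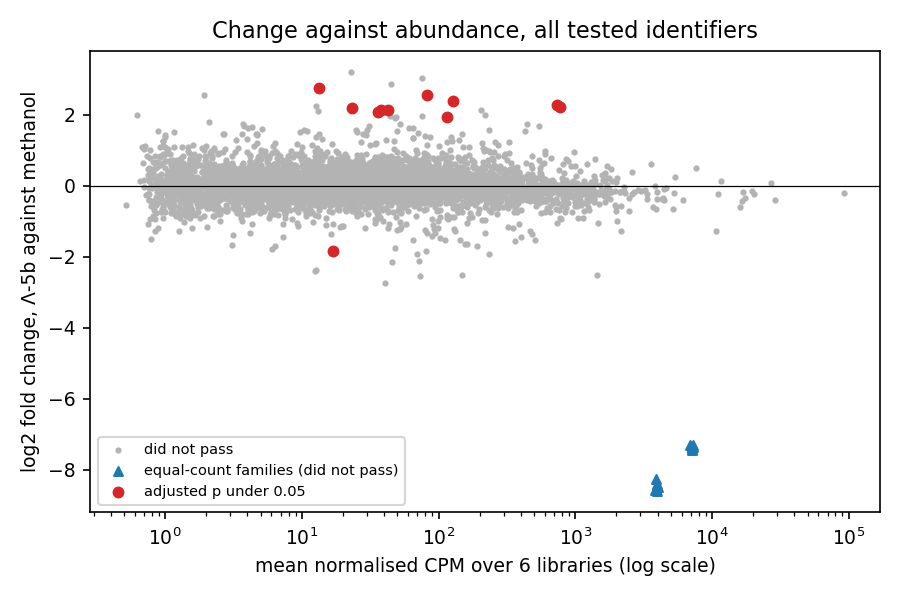
Fitted log2 fold change (Λ-5b against methanol, y axis) against mean normalised CPM over the 6 libraries (x axis, log scale) for the 4950 tested identifiers. Red points are the 10 that rose and the 1 that fell at the adjusted p threshold of 0.05, and blue triangles are 14 identifiers in 2 families with equal counts, which lie far below 0 and did not pass.

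The 5 neighbouring identifiers that rose belonged to a run of 7 measured identifiers that was higher as a whole. The run extended from 4 numbers below ECs2110 to 3 numbers above it, and the files hold 7 identifiers in this span of 8 numbers. All 7 were higher in every culture. Their fitted log2 fold changes lay between 2.14 and 3.21 with a median of 2.55, and the median over the run was 2.24, 2.19 and 3.07 in cultures 1, 2 and 3. The members differed widely in abundance, from 13.4 to 739 mean CPM. The remaining 2, including the member with the value of 3.21, did not pass at an adjusted p of 0.112 (edgeR). Their log2 changes were 4.64 and 4.29 in culture 3, against 1.88 to 2.89 in the other cultures. The 17 tested identifiers within 10 numbers on either side of the run had a median log2 fold change of -0.25, and none of them passed (edgeR, smallest unadjusted p = 0.0137). The run and its limits were chosen after its values were seen.

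**Figure D2:**
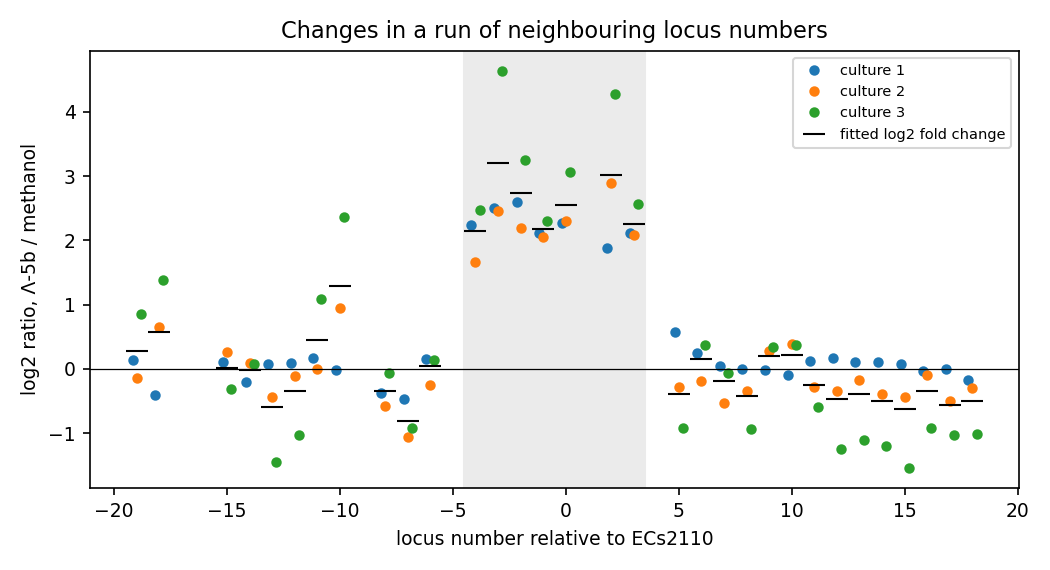
Log2 ratio of Λ-5b to methanol (y axis) for tested identifiers, ordered by locus number relative to ECs2110 (x axis). Coloured points are the 3 cultures, black bars are the fitted log2 fold changes and the shaded band marks the run, whose 7 members lie between 2.14 and 3.21 while the flanking identifiers scatter around a median of -0.25.

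Large differences in the same direction in every culture were counted beside the test. Without the 14 identifiers in the families with equal counts, 27 identifiers were at least 2-fold higher in every culture and 6 were at least 2-fold lower in every culture, out of 4936. Among the 27, the median log2 fold change was 1.97 and 10 passed the test. Among the 6, the median was -2.27 and 1 passed. When the direction of culture 1, 2 or 3 was reversed in turn, the corresponding counts of identifiers changed in every culture were 3, 1 and 1, against 33 for the actual direction. The 27 held all 7 members of the run, and neighbouring identifiers changed together, so the 33 are not independent of each other. Mean abundance went down to 1.91 CPM among the 27 and to 3.08 CPM among the 6. Without a minimum size, 1509 identifiers (30.6%) had the same direction in every culture, which was fewer than the 1714 (34.7%) with culture 1 reversed, and the counts were 672 and 1041 with culture 2 or 3 reversed. These counts were added after the data were examined.

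The differences between the treated and control parts were counted in each culture, which holds 1 library of each kind, so that no test between cultures was possible. In culture 3, 569 identifiers were at least 2-fold higher and 433 at least 2-fold lower in the treated part, outside the families with equal counts. The corresponding numbers were 221 and 132 in culture 1 and 137 and 92 in culture 2. Across the 4936 identifiers, which are not independent replicates, the log2 changes of cultures 2 and 3 correlated at r = 0.41, those of cultures 1 and 2 at r = 0.16 and those of cultures 1 and 3 at r = 0.05. The rank correlations were 0.41, 0.08 and -0.09 in the same order. The treated library of culture 3 had the lowest mean correlation with the other 5 libraries, 0.949, against 0.965 to 0.969 for the others. At an unadjusted p under 0.05, the test with culture as a block returned 405 identifiers, 225 higher and 180 lower, against 247.5 expected if none changed. When the 6 libraries were regrouped 3 against 3, the other 3 splits that part the libraries of every culture returned 44, 80 and 376. Splits that part 1 culture alone returned 90 for culture 1, 47 for culture 2 and 1228 for culture 3.

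Identifiers with a prefix other than ECs did not pass the test. The prefix pO157 is also the name of the large virulence plasmid of this serotype, and its 74 tested identifiers had a median log2 fold change of -0.02, with a range from -0.79 to 0.61. The 3 identifiers with the prefix pOSAK1 had a median of 0.28, and the 7 with the prefix ECp had a median of -0.13. None of these 84 identifiers passed, and 1 of them, with the prefix pO157, had an unadjusted p under 0.05 (edgeR). Among the 4866 with the prefix ECs, 11 passed and 404 had an unadjusted p under 0.05. At that share of passes, an absence among 84 does not set these prefixes apart. No prefix group passed as a set (camera with a preset correlation, adjusted p = 0.595 for each, and adjusted p = 0.666 for each with an estimated correlation). Identifiers with the prefix pO157 took 0.895% ± 0.0225 (SD, n = 3) of the counts outside the families with equal counts in control libraries and 0.918% ± 0.0561 in treated libraries. The exact two-sided permutation test, which ignored the pairing by culture, gave p = 0.5. For such a test 0.1 is the smallest p that 3 against 3 libraries allow.

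The largest differences in level lay in 2 families of 7 identifiers each, whose members had nearly equal counts within every library. Together these 14 identifiers took 26.3% of the counts in control library 1 (Wilson 95% interval 26.27 to 26.32) and 11.8% in control library 2 (11.78 to 11.82), but 0.300% in control library 3 (0.297 to 0.303). Their share in the treated libraries was 0.0411% (0.0399 to 0.0423), 0.0302% (0.0293 to 0.0311) and 0.0485% (0.0475 to 0.0495). These intervals cover counting error only. Every control library was above every treated library. The exact two-sided permutation test, which regrouped the 6 libraries without regard to culture, gave p = 0.1, the smallest p that this regrouping allows. No test within cultures was made. The fitted log2 fold changes were between -8.61 and -7.31, and none of the 14 passed (edgeR, smallest adjusted p = 0.469). The share in the control libraries alone ranged over 87.5-fold. All 14 passed in the DESeq2 fit, and in edgeR they passed without culture 3 and in the fit without both the block and control library 3.

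**Figure D3:**
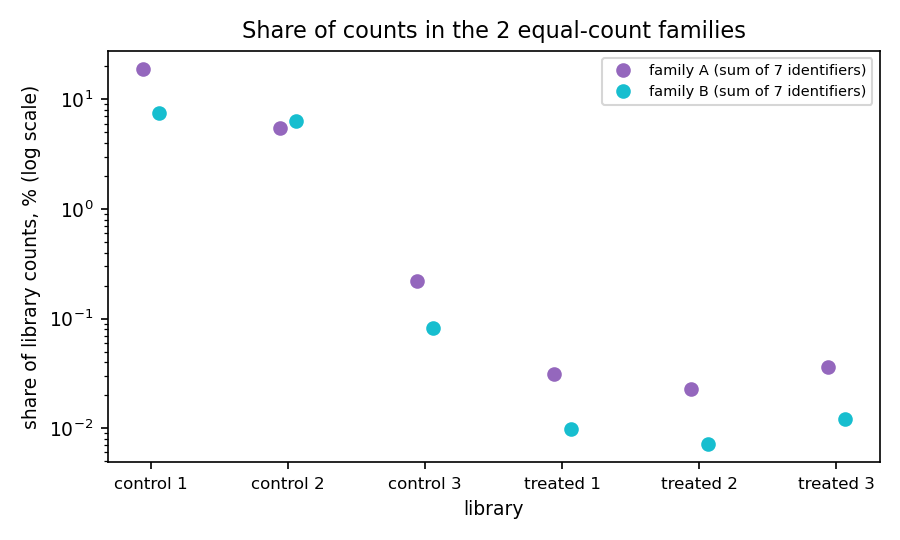
Share of library counts, in percent on a log scale (y axis), taken by each of the 2 families of 7 identifiers with equal counts in the 6 libraries (x axis); each point is the sum over 7 identifiers in 1 library. Control libraries 1 and 2 lie above 5% for each family, control library 3 holds 0.219% and 0.0818%, and the treated libraries hold at most 0.0364%.

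The count of changed identifiers depended on which culture entered the fit, and each fit without a culture rested on fewer pairs. It was 0 without culture 1, 39 without culture 2 and 127 without culture 3, and DESeq2 with the same design returned 88, of which 45 were higher and 43 lower. All 11 identifiers called by edgeR were among the 88. The 14 members of the families with equal counts were among the 43 lower calls of DESeq2, and among the 127 calls without culture 3. The median log2 change of the run was 2.67, 2.68 and 2.29 without culture 1, 2 and 3, against 2.55 in the reported fit. The run therefore kept its size also where no identifier passed.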

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

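The number of changed identifiers depended on the cultures and on the tool more than on scaling or filtering. Against 11 in the reported fit (10 higher, 1 lower, 11 at least 2-fold), the fit with no replicate block called 28 (25 higher, 3 lower, 28 at least 2-fold), DESeq2 88 (45 higher, 43 lower, 87 at least 2-fold) and scaling by library totals alone 17 (16 higher, 17 at least 2-fold), and each of these held all 11. Library totals alone moved the median log2 change of all identifiers to 0.34. Leaving out 1 culture gave 0 to 127 calls (0 to 77 higher, 0 to 50 lower, 0 to 94 at least 2-fold), with 10 of the 11 kept without culture 2, 11 kept without culture 3 and 0 calls, with 689 at an unadjusted p under 0.05, without culture 1. In the fit without the block, leaving out control library 1, 2 or 3 gave 10 (8 higher, 2 lower), 0 and 30 (15 higher, 15 lower) calls, and leaving out treated library 1, 2 or 3 gave 53 (46 higher, 7 lower), 35 (26 higher, 9 lower) and 31 (27 higher, 4 lower), all at least 2-fold. Without control library 2, 339 identifiers had an unadjusted p under 0.05 (edgeR). The 14 members of the families with equal counts were among the 43 lower calls of DESeq2 and the 50 lower calls without culture 3. They were also among the 15 lower calls without the block and control library 3. The single-library fits were chosen after the data were seen, and the cause of the differences was not tested. DESeq2 size factors in edgeR, upper-quartile factors, limma-voom, both other filters, leaving out the 10 most abundant identifiers and leaving out the families with equal counts gave 11 to 13 calls that held all 11. The log2 change of ECs2110 stayed between 2.29 and 2.88 over 19 alternatives and that of ECs3958 between -1.94 and -1.52, each past the threshold in all but 2 of them (without culture 1, and without the block and control library 2). ECs3956 passed in 7 of 19. The median of the run of 7 neighbours stayed between 2.29 and 2.88. The count at least 2-fold changed in every culture was 47 with the 14 members of the families and 33 without them, ranged from 44 to 65 under other scalings, filters and prior counts, and was 67 to 114 with only 2 cultures required. Camera and fry on the fixed gene lists, and leaving out named structural RNAs, were not run because no identifier matched a symbol. Depth limits the low end: ECs2108 rested on 26 counts in its smallest library.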

Other observations

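Some groups of neighbouring identifiers had unlike values in the 3 cultures, a difference that was not tested. When ECs identifiers were divided into blocks of 20 consecutive numbers, a block of 20 tested members had a median log2 change of 2.04 in culture 1, against -0.07 in culture 2 and -0.33 in culture 3. A block of 14 members had a median of -1.84 in culture 3, against -0.01 and -0.08 in cultures 1 and 2. Neither block held an identifier that passed the main test. Of 279 blocks, 10 passed camera with a preset correlation (3 higher, 7 lower). With an estimated correlation 0 passed (camera, smallest adjusted p = 0.97), and 0 blocks had an unadjusted p under 0.05. Chance alone would give some such blocks among 279, so this test was too strict here to count against the preset calls. With fry in place of camera 0 passed. The preset count was 6, 13 and 17 without culture 1, 2 and 3. It was 5 with blocks shifted by 10 numbers, 20 with blocks of 10 and 6 with blocks of 40. In the 10 splits of the 6 libraries, 5 gave at least 10 blocks, the real split included, and the highest other split gave 18. Of these 5, 2 part only culture 1 and are the same fit counted again, because culture is a block. The block counts therefore do not set the treatment apart from other groupings. These blocks, and the tests of the placement of the rises, of the run's flanks and cultures, of the share among controls and of equal counts, of other splits for the identifiers, and of consecutive numbers, were chosen after the results were seen.

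The log2 changes of consecutive locus numbers correlated across identifiers (Spearman rho = 0.357 over 4426 pairs of numbers, permutation p = 1e-04, the smallest that 10000 permutations can give). The correlation was 0.178 for numbers 2 apart and 0.0456 for numbers 5 apart. This is consistent with locus numbers that follow gene order and with neighbours that share transcripts, a hypothesis that coordinates would settle.

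In the run of 7 neighbours, of which 5 passed the test, 5 of the 10 rises lay within 8 numbers. Random placements of the calls held at most 3 in any such window (10000 placements, permutation p = 1e-04, the smallest possible). This excludes nothing, because the window was taken from the run and the placements ignore the correlation of neighbours, so chance placement stays open. The run was higher in each of the 3 cultures, with a lowest culture median of 2.19. This is no test of a single responding culture, because the run was chosen through calls that favour like changes in all cultures. Template DNA or a higher copy number of the wider region would raise the flanks as well, whose median was -0.25. The run was cut at its outermost passing identifiers after its values were seen. This favours low flanks, so their median does not decide the question. A gain in copies limited to the run itself was not tested. A common response to Λ-5b of 1 or more neighbouring transcription units remains as a hypothesis, found and examined on the same data.

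The 2 families with equal counts may be transcripts of multicopy genes whose reads were divided evenly among identical copies, for which ribosomal RNA left after depletion is a candidate. The median coefficient of variation of counts within a family and library was 3.31%. This cannot count for the explanation, since the equal counts were what prompted it, and multicopy transcripts stay an open hypothesis. Treatment cannot account for the spread among the control libraries, where the highest share was 87.5 times the lowest. That spread was part of the pattern as first seen, so it is no test of the gap between control and treated libraries. A part for treatment stays open, since the lowest control share was still 6.19 times the highest treated share and depletion efficiency was not recorded. The families do not account for the 11 calls, as all 11 were called when the families were left out before scaling.

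Treated library 3 stood apart from the others. Depth is argued against, since its mean correlation with the other libraries was 0.946 after all libraries were thinned to the smallest total, below the 0.964 to 0.968 of the others. The families with equal counts are argued against as well, since without them its mean correlation was 0.955, against at least 0.972. A difference in how culture 3 grew or responded cannot be told apart from handling of this library, because there is 1 such library.

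Chance could not be assessed by regrouping for the count of identifiers, since 10 splits of 6 libraries cannot give a share under 0.05. Of these splits, 3 gave at least 11 calls, the real one with 11 included. The other 2, with 289 calls each, part only culture 3 and are the same fit counted again, because culture is a block. They set the change in culture 3 against the spread of the other cultures, and they point to that structure. Among the 4 splits that part all pairs, the real one gave 11 and the others 0, while at an unadjusted p under 0.05 the real one gave 405 and the others 44, 80 and 376 (edgeR).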
